A study of Oryzias latipes with 10 samples.

How the data were processed

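Whole-brain RNA of 10 adult male medaka, 5 per group, was hybridised to 1-colour Agilent arrays, 1 fish per array. Per the labels' protocols, fish came from a dealer and were kept outdoors, RNA was prepared per fish with an RNeasy kit, and Cy3-labelled cRNA was made with a low-input amplification kit. The groups and the replicate numbers 1 to 5 were taken from the labels, which state a separate fish per sample and no pairing of fish across groups.

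Per the file headers, each array was scanned and its spots quantified with Agilent Feature Extraction 12.0.3.1, whose processed signal is an intensity on a linear scale after background subtraction and detrending within the array, with no normalization between arrays. The deposited series table holds the authors' log2 values for the same arrays. Set against the scanner values, these had a slope of 1.00 and r of 1.00 with log2 processed signal minus the array's 75th percentile, centred on each probe's median over the 10 arrays, so their scale, centring and direction could be worked out. The medians of its 10 columns over all rows lay between -0.011 and 0.022. Other scanner columns, which flag spots as control, well above background, saturated or outlying, were used as the authors deposited them.

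The main values were log2(processed signal) minus each array's 75th percentile over spots other than controls. Spots of 1 probe were averaged on the log2 scale, which concerned 12713 of the 31090 probes printed on 2 spots each. Spots with an outlier flag were left out, which removed 9 probes with no remaining value on some array. A probe was tested when it was well above background on at least 5 of the 10 arrays, chosen without regard to group, which left 28376 probes of 25670 identifiers. An identifier with several tested probes was represented by the one with the highest mean level. Such a filter and the 75th percentile scaling mean that a shift shared by most transcripts cannot be seen, and that fold changes of dim probes rest on signals near the background.

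Differences are SC minus LW. They were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided and without a covariate, with Benjamini-Hochberg adjustment over the tested probes. Files were read with the data.table package, version 1.17.8, and figures were drawn with matplotlib 3.10.9. For a probe not well above background on any array of a group, the fold is given as a bound. It sets the brighter group's mean against, on each array, the higher of the background floor, which is the lowest signal of any spot well above background on that array, and the probe's own signal. Where a probe was not well above background on some arrays of a group, those arrays alone were set at this floor for the values named as such. Single values were compared between groups with exact permutation tests. Co-varying probe groups were found by average linkage at a correlation of 0.7 among probes with a within-group SD over 1.5, with at least 10 probes per group, and their folds compare an array's median over the probes with the median of that value in the 5 lowest arrays, with probes not well above background set at the floor.

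On data simulated with the real means and spreads for SC against LW (28376 probes, 50 changed at each size), the fit recovered 6 of 50 changes of 0.5 on the log2 scale, 31 of 50 of 1, 40 of 50 of 2 and 48 of 50 of 3. It called 7 of 28176 unchanged probes. The step that finds probe groups recovered 40 of 40 planted probes. Small changes can therefore be missed at this number of arrays. A small share of the probes was changed in the simulation, while 30.9% of identifiers passed in the data. The Benjamini-Hochberg cutoff is stricter when fewer probes change. Neither the recovery rates nor the count of unchanged probes called therefore carries over to the data. Probes were also drawn independently, with the same SD in both groups.

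The array's 27793 identifiers are clone or cluster names in 27051 cases and transcript identifiers beginning with ENSORLT in 723. A further 19 are accessions or a symbol, and of these 1 is a gene symbol and 1 matched the reference's list of genes (assembly ASM223467v1). Of 1410 symbols in 35 gene lists fixed before the data were examined, 0 matched an identifier, so the planned set tests on those lists and the cell type markers could not be run. The rule for named genes, also fixed before, was the 8 genes with a symbol and the highest and the 8 with the lowest log2 difference among those past the threshold with groups that do not overlap, up to 2 members per list, and cirbp, rbm3, tshb, cga, dio2, gnrh1, nfe2l2 and keap1 where tested. No gene with a symbol passed the threshold, and of the fixed names none matched exactly. TSHB2 and LOC101158465 are reported as the identifiers with a symbol. The 2 identifiers with the highest and the 2 with the lowest log2 difference among those past the threshold with groups that do not overlap, each by its brightest tested probe, were added after their values were seen. No gene name was inferred from a sequence, and positions in the genome are not used here.

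The alternatives fixed before the data were examined were normexp background correction, quantile normalization, median centring, no filter or a stricter filter on dim probes, the authors' values, the slide as a block, the replicate number as a block, array weights, a variance model with trend and robust fitting, the mean of an identifier's probes, and leaving out each array in turn. Added after seeing the data were the slide as a random block, slide 2 alone, leaving out SC replicates 2 and 3 together, removing each array's trend with probe GC content, and normexp without an offset.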

Results

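Gene expression was measured in whole brains of adult male medaka (Oryzias latipes), a small freshwater fish, with 1-colour Agilent oligonucleotide arrays. The 5 fish of the LW group stayed under long days and warm water, with 14 h of light, 10 h of dark and 26 °C. The 5 fish of the SC group had been moved from those conditions to short days and cool water, with 10 h of light, 14 h of dark and 10 °C. Brains were taken 2 weeks after the transfer, at the middle of the light phase, and RNA was prepared from each fish, so that 1 array stands for 1 fish. Day length and temperature changed together, and as described the SC fish alone were moved. The comparison therefore measures the joint difference of light, temperature and transfer, and slides were partly tied to the groups. Each array held 43803 spots other than controls, of which 89.2% to 92.3% lay well above background, and no such spot was saturated. The 75th percentile of the processed signal averaged 1135 ± 63.5 (SD, n = 5) in LW and 1127 ± 146 (SD, n = 5) in SC, which did not differ (two-sided exact permutation p = 0.897). The SD of a single spot, worked out from the 2 spots of a probe on the same array, was 0.109 on the log2 scale. It covers 11027 probes well above background on all 10 arrays, so dim probes are left out. The number of arrays limits the precision of every value.

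The design addresses which brain transcripts differ between winter-like and summer-like conditions. Of 25670 identifiers tested, 7932 (30.9%) differed between the groups at an adjusted p under 0.05 in the limma fit, counting 8727 of 28376 probes. Among them 3815 were higher in SC and 4117 were lower in SC. An identifier here is the clone, cluster, transcript or gene name that the array's design gives a probe, and it takes the place of a gene. The files pair almost none of these with gene symbols, so the changed transcripts are described by number, size and level, and TSHB2 is the single one with a symbol of its own in the files. Most changes were small, with a median absolute log2 difference of 0.69 among the called identifiers, and the median difference over all tested identifiers was -0.0031. The SC and LW arrays did not overlap for 6067 of the tested identifiers (23.6%), where chance gives 0.794%, and 5775 of these were among the called ones.

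A change of at least 2-fold together with an adjusted p under 0.05 was found for 2013 identifiers, of which 1032 were higher and 981 lower in SC. The balance between the directions shifted with the size of the change. At 4-fold or more, 220 identifiers were higher and 113 lower in SC, and at 8-fold or more 73 were higher and 11 lower. Of the 73, 22 were very variable between fish of 1 group (within-group SD over 1.5 on the log2 scale), and 18 of these belong to a group of probes bright mainly in SC replicates 2 and 3, described with the probe groups. Without the very variable identifiers the counts were 51 against 10. With normexp background correction and an offset of 50 added before the logarithm, the 2-fold count was 1072, with 564 higher and 508 lower, and with normexp and no offset it was 1607. At 8-fold or more, normexp left 26 higher and 1 lower with the offset and 44 and 3 without it, a filter for probes well above background on all 10 arrays left 48 and 6, and leaving out SC replicates 2 and 3 together gave 72 and 24.

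**Figure D1:**
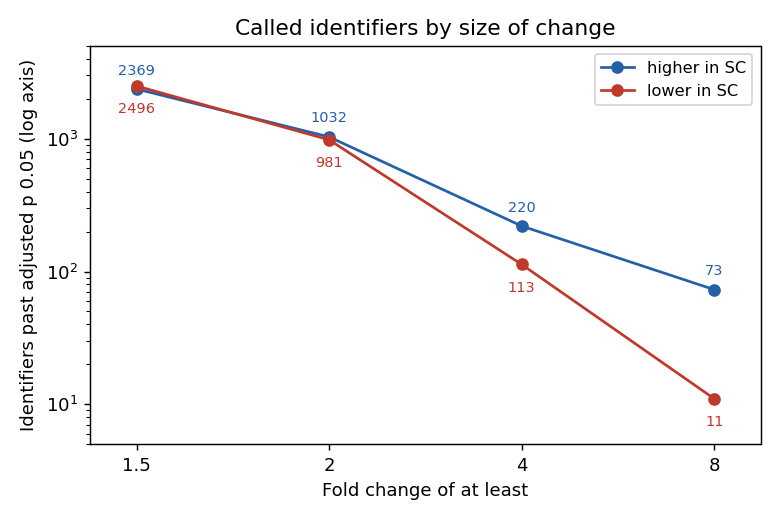
Number of identifiers past an adjusted p of 0.05 (y axis, log scale) against the least fold change required (x axis), higher in SC in blue and lower in SC in red. The counts are near each other at 2-fold, 1032 and 981, and part at 8-fold, 73 and 11.

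Of the called identifiers whose groups did not overlap, the 2 with the highest and the 2 with the lowest log2 difference are given as examples, each by its brightest tested probe. They were chosen after their values were seen. In SC, dola:8748 had processed signals of 196 to 540 in the 5 brains, while it was well above background in 1 of the 5 LW brains. It was at least 33.3-fold higher in SC with the other 4 LW arrays set at the background floor (fitted log2 difference 6.52 ± 0.51, SE, n = 5 and 5, adjusted p = 3.33e-05 in limma). Its probe has the sequence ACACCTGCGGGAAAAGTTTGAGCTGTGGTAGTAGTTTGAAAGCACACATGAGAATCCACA. The identifier dola:19514 was well above background in 5 of 5 SC and 4 of 5 LW brains, and was higher in SC by 5.89 ± 1.09 on the log2 scale (SE, adjusted p = 0.00308). Without LW replicate 1, the LW brain not well above background, the difference was 4.84 (28.7-fold), and without SC replicate 5 it was 6.51. Its probe is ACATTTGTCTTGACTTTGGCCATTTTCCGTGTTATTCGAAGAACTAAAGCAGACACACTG. In the other direction, OLA03-Oa06 was well above background in 5 of 5 LW brains and in 0 of 5 SC brains, and was at least 7.13-fold higher in LW (fitted log2 difference -5.05 ± 0.55, SE, adjusted p = 0.000184). Its probe is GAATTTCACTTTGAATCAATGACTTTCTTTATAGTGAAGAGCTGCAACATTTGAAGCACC. The identifier olea62l03 fell by 4.14 on the log2 scale (SE 0.63, adjusted p = 0.00105), from -0.93 ± 0.84 (SD, n = 5) in LW to -5.08 ± 1.33 (SD, n = 5) in SC, and a second probe of it gave -3.15 ± 0.37 (SE, adjusted p = 0.000261). Its brighter probe is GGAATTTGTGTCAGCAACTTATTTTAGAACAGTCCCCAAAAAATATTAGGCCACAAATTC. With the slide as a block, the differences were 7.17 (adjusted p = 0.0120 in limma), 5.33 (0.163), -5.46 (0.0361) and -4.35 (0.0733) in the order given. Within slide 2 they had these same sizes. On that slide dola:8748 was not well above background in the LW array, nor OLA03-Oa06 in the SC arrays. The 7.17 and -5.46 are therefore set against background signal and are not measured sizes. With normexp the differences of the named identifiers, in the same order, were 2.76, 4.38, -1.26 and -2.77 with the offset. Without it they were 5.04, 5.31, -2.90 and -3.73. Each was past an adjusted p of 0.05 in limma.

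TSHB2, whose symbol stands for a beta subunit of thyroid-stimulating hormone, a pituitary hormone that acts on the thyroid, was dim and did not pass the test. The labels do not say whether the pituitary was part of the brain samples, or was so in every fish. It was well above background in 4 of 5 SC brains and in 1 of 5 LW brains, a difference in detection that did not pass Fisher's exact test (two-sided p = 0.206). Its mean level was -5.99 ± 1.94 (SD, n = 5) in SC and -8.00 ± 1.92 (SD, n = 5) in LW, a log2 difference of 2.01 ± 1.09 (SE, adjusted p = 0.193 in limma), or of 0.89 with the arrays that were not well above background set at the background floor. Without LW replicate 3, the one LW brain with a signal, the difference was 2.85 and the adjusted p 0.0426. No LW brain was then well above background, so 2.85 is set against background signal and is not a measured size. Without SC replicate 5, the one SC brain with none, it was 2.81 with an adjusted p of 0.0494. With normexp the difference was 0.37 with the offset and 1.01 without it. It was 3.89 both with the slide as a block (adjusted p = 0.299 in limma) and within slide 2. Both draw on LW replicate 5, where TSHB2 had a signal of 2.03 and was not well above background. The 3.89 is therefore set against background signal and is not a measured size. The TSHB2 probe is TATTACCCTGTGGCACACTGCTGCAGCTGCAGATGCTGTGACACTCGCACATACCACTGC. LOC101158465, the single identifier that matched the reference table, had a log2 difference of -0.13 ± 0.57 (SE, adjusted p = 0.888), with a signal well above background in 4 of 5 brains of each group.

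**Figure D2:**
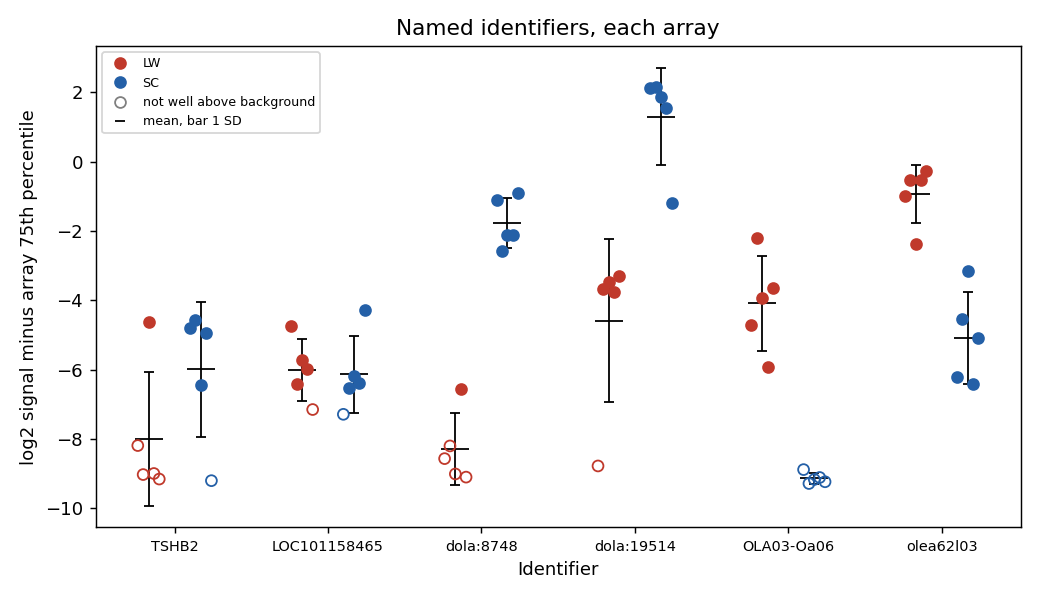
Level of 6 identifiers on each array (y axis, log2 signal minus the array's 75th percentile), LW in red and SC in blue, open circles not well above background, with the mean and 1 SD as black bars (n = 5 per group). TSHB2 was well above background in 4 SC brains and 1 LW brain, while the groups did not overlap for the 4 clone or cluster identifiers on the right.

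In all, 48 probes were well above background in all 5 SC brains and in none of the 5 LW brains, and 12, with OLA03-Oa06 among them, showed the reverse. The bounds on the fold had a median of at least 2.30-fold for the 48 and at least 2.82-fold for the 12, with highest bounds of 102-fold and 7.13-fold. The probe at 102-fold is the dimmer of 2 probes of its identifier, so it was not among the examples, which were ranked on the fitted difference of the brightest probe.

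For 2706 identifiers that had 2 tested probes, the log2 differences of the brighter and the dimmer probe correlated across identifiers, which are not independent replicates, with r = 0.777 and rho = 0.784. The brighter probe was past the threshold for 846 of them. The other probe had the same direction for 803 (94.9%), was itself past the threshold in that direction for 590, and was past it in the opposite direction for 11.

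The brains separated by condition along the first principal component, which held 37.0% of the variance. Correlations across probes were 0.973 to 0.978 between LW brains, 0.960 to 0.976 between SC brains and 0.941 to 0.960 between the groups. The SC brains differed more from each other than the LW brains did. The median SD of a probe was 0.275 in SC and 0.205 in LW on the log2 scale, and the SD was larger in SC for 67.5% of probes. The mean distance of an array from the mean of its group's other arrays was larger in SC, at 0.588 against 0.505. An exact permutation of these distances gave a two-sided p of 0.00794, the smallest that 5 against 5 can give. It takes the distances as independent, although those of 1 group share arrays, so this p does not measure a difference in spread. SC replicate 1 lay farthest from its group, at 0.667. Without SC replicate 1, the median SD in SC was 0.234, and the SD was larger in SC for 57.6% of probes.

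**Figure D3:**
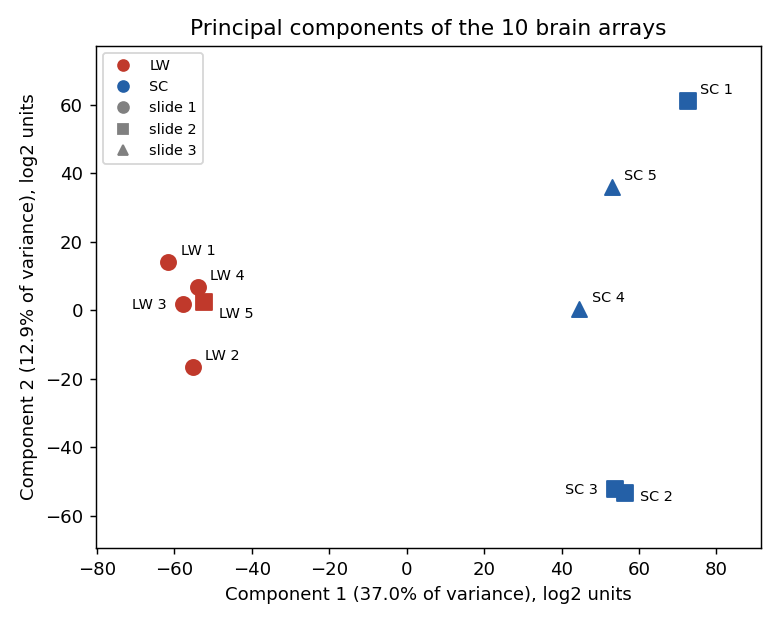
First and second principal components of the tested probes (axes in log2 units), LW in red and SC in blue, with the slide shown by the symbol. The groups separate along the first component (37.0% of variance), on which LW replicate 5 lies with the other LW arrays although it shares slide 2 with SC replicates 1 to 3.

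Some probes rose together on single arrays. The largest such group held 123 probes, of which 78 were tested between conditions and 23 passed, against 8727 of 28376 over all tested probes. The 123 were picked for a large within-group SD, so the 23 say little about the conditions. The group's median level was 49.6-fold above the baseline arrays in SC replicate 2, 30.7-fold in SC replicate 3 and 3.20-fold in SC replicate 1. SC replicates 2 and 3 were at positions 3 and 4 of slide 2. Probe group 2 held 29 probes, whose median was near the background floor on the other arrays and at least 11.0-fold above it in LW replicate 5 and at least 27.3-fold in SC replicate 1. These arrays were at positions 1 and 2 of slide 2. Whether the fish or the place on the slide was the source was not tested. Probe group 3 held 27 probes, at 26.0-fold in LW replicate 2 and 26.8-fold in SC replicate 3. Of these, 13 probes of group 2 and 18 of group 3 were well above background on enough arrays to be tested between conditions, and none of them passed in limma (0 at an unadjusted p under 0.05). Probes picked for a large within-group SD that rise in 1 array of each condition can hardly pass, so this says little about the conditions. These groups were found after seeing the data.

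**Figure D4:**
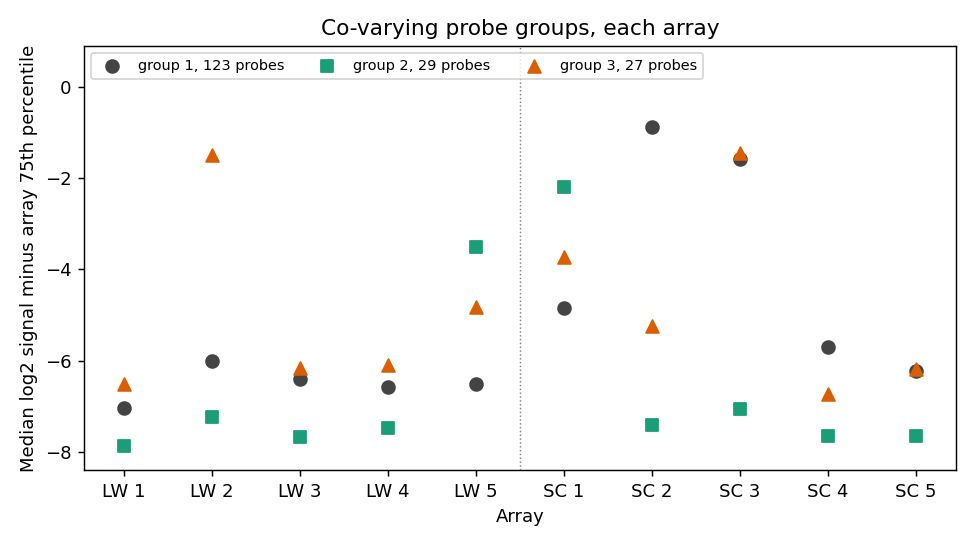
Median level of the probes of 3 co-varying groups on each array (y axis, log2 signal minus the array's 75th percentile; x axis, the arrays, with LW left and SC right of the dotted line). Group 1 was highest in SC replicates 2 and 3, group 2 in LW replicate 5 and SC replicate 1, and group 3 in LW replicate 2 and SC replicate 3.

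Slides were partly tied to the groups. Slide 1 held LW replicates 1 to 4, slide 2 held LW replicate 5 with SC replicates 1 to 3, and slide 3 held SC replicates 4 and 5. With the slide as a block, which draws the difference from slide 2 alone, 1122 identifiers passed, with 602 higher and 520 lower in SC, and 898 of them changed at least 2-fold (498 higher, 400 lower, and 84 and 23 at 8-fold or more). Of the 1122, 1020 were also among the 7932. Within slide 2, 1 LW array against 3 SC arrays gave 0 identifiers past the threshold in limma and 3262 at an unadjusted p under 0.05. As a check on arrays outside slide 2, 4795 probes differed between the LW arrays of slide 1 and the SC arrays of slide 3. Of them, 4483 (93.5%) had the same direction between SC and LW within slide 2. Across these probes the 2 differences correlated with r = 0.726. Those within slide 2 were smaller, with a slope of 0.663 on those between slides 1 and 3. The probes were picked for passing between slides 1 and 3, which inflates their differences there. The slope therefore does not measure a slide effect. All differences within slide 2 share LW replicate 5, so the probes are not independent checks.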

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

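The comparison with other splits of the samples was planned. All other tests in this part were chosen after the results were seen. The gap tests, run on 24 sets of 5 arrays, picked out 5 values. Chance would give about 1.2 for sets chosen without regard to their values. Many sets were probe groups picked for a large within-group SD or identifiers picked for extreme differences. All values picked out except that of TSHB2 came from such sets, so the chance figure does not apply to them.

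A single array stood far from the rest of its group in these cases. TSHB2 was at -4.63 in LW replicate 3, above the other LW arrays. The identifier dola:19514 was at -8.77 in LW replicate 1 and at -1.18 in SC replicate 5, each the lowest of its group. Probe group 2 (29 probes) had a median of -3.51 in LW replicate 5 and of -2.19 in SC replicate 1, each the highest of its group.

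The first pattern weighed is the number of identifiers that differ between SC and LW. Of 100 splits of the 10 arrays into 5 and 5, drawn from 126, 1 called as many as the real one (7932), which was the real one itself. The highest of the others called 5, which argues against an arbitrary division of the arrays as the source. A mixed split adds the difference between the conditions to the spread within its groups, so its count is low for that reason too. The splits also do not keep to the slides. A slide effect as the whole cause is argued against by LW replicate 5, which lay at 0.151 on an axis from LW on slide 1 (0) to SC on slide 3 (1), while SC replicates 1 to 3 of its own slide lay at 0.887, 0.759 and 0.795. Neither array brightness (exact permutation p = 0.897) nor probe GC content (Spearman correlation across probes with the log2 difference 0.0442, and 7882 identifiers called after removing the GC trend) separates the groups. What stays open is how much each single fold owes to the slide. A difference between the conditions is a hypothesis these values leave standing, and the design does not part its light, temperature and transfer components.

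The second pattern is a group of 123 probes that rose together in 2 SC brains. The median level was 49.6-fold and 30.7-fold above the baseline arrays in SC replicates 2 and 3, and 3.20-fold in SC replicate 1. An effect shared by all arrays of slide 2 is argued against by LW replicate 5. Its median rise over LW replicates 1 to 4 was 0.0308 on the log2 scale. With dim probes set at the background floor it was -0.123, against 4.57 in SC replicate 2. SC replicates 2 and 3 were at positions 3 and 4 of that slide, and LW replicate 5 at position 1. An effect of position within the slide was not tested and remains open. Other tissue carried along at dissection may be a source and remains open, since probes picked from SC replicate 2 alone (106) differed between SC replicates 3 and 2 with an SD of 1.51 on the log2 scale, between the bound of 1 set for a single added tissue and that of 2 set against it. No gene name or marker is available to decide it, and a response to SC conditions in some fish is untested.

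The third pattern is the larger spread among SC brains. A slide effect is argued against by the LW arrays, where the mean correlation across slides lay 0.0014 below that within slide 1, against a gap of 0.00886 between LW and SC. Very variable probes are argued against as its cause by the distances of the arrays from their group. Without those probes the mean distance fell from 0.505 to 0.416 in LW and from 0.588 to 0.498 in SC. The difference between the groups was 1.00 times its size with them. The exact permutation p of 0.00794 takes distances that share arrays as independent, so it does not measure this difference. Part of the larger spread may come from SC replicate 1. Without that array the ratio of median SDs (1.34 with all arrays) was 1.14, between the bounds set for and against an outlying array. The farthest SC array was left out while all LW arrays were kept, so this ratio leans low. A larger difference between fish under SC conditions was not tested.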

How the results depend on the processing

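The slide as a random block, slide 2 alone, leaving out SC replicates 2 and 3, GC trend removal and normexp without an offset were chosen after seeing the data. The called count and its split kept within 1.5 times of 7932 under every setting run except the slide block and slide 2 alone, from 6179 with the replicate block to 9646 with the slide as a random block (consensus correlation -0.103). With the slide as a block there were 1122 identifiers and 1261 probes, 602 higher and 520 lower. At least 2-fold were 898, with 498 higher and 400 lower, and 23 were at least 8-fold lower. That fit draws on slide 2, which holds 1 LW array. Slide 2 alone gave 0 for each of these counts in limma, with 3262 at an unadjusted p under 0.05 and fewer arrays (4). Under normexp the 2-fold counts were 1072, with 564 higher and 508 lower, and the 8-fold counts 26 and 1. Without the offset, normexp gave 1607 at 2-fold and 44 and 3 at 8-fold, so the background model and the offset each lowered the counts. The stricter filter gave 48 and 6 at 8-fold, having removed dim probes, and 24 were 8-fold lower without SC replicates 2 and 3, where the cause was not tested. Leaving out single arrays gave 6593 to 7804 identifiers (7282 to 8589 probes, 3163 to 3693 higher, 3430 to 4111 lower). The 2-fold counts were then 1889 to 2064 (965 to 1073 higher, 917 to 1007 lower), and 65 to 87 were 8-fold higher and 10 to 16 lower. No scaling moved the median of all identifiers by 0.1 or the share of higher calls by 10 percentage points. Each scaling brings the arrays to a common level, which holds that median in place. This therefore says little about the balance of directions or about a shift shared by most transcripts.

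With the replicate block, which treats equal numbers as pairs, 6179 identifiers passed, 5876 of them among the 7932. Same-numbered arrays correlated at -0.032 to 0.0732 in their deviations, and 1 of 5 LW arrays correlated best with its own number, so the numbers were not taken to pair fish.

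The 4 clone or cluster identifiers named kept their direction in every setting that tested them, and lost the threshold in 2 cases with the slide as a block. Slide 2 alone gives the same differences as that block (7.17, 5.33, -5.46 and -4.35) and says nothing about their calls. Of these, 7.17 and -5.46 are set against background signal. TSHB2 passed in 2 settings, without LW replicate 3, where no LW array was well above background, and without SC replicate 5. In the OLA series of identifiers, 35.2% of the called ones were higher in SC, and 50.9% with the slide as a block; the cause was not tested. The gene list tests, cell type markers and scan date as a block (each slide was 1 scan) were not run. The stricter filter left out TSHB2, LOC101158465, dola:8748, dola:19514 and OLA03-Oa06, which were near background on some arrays and are limited by it.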

Other observations

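The series tests and probe groups in this part were chosen after seeing the data. Besides the 3 probe groups of the report, other probes switched together on single arrays of both groups. Of 29783 probes, 624 (2.10%) had a within-group SD over 1.5 on the log2 scale, and 267 of these fell into 10 co-varying groups of at least 10 probes. Another 13 probes, group 6, had medians of -3.60, -4.37 and -4.35 in LW replicate 5, SC replicate 4 and SC replicate 5, and between 0.57 and 2.29 on the other 7 arrays. A set of 10 probes, group 9, had a median of -8.03 in LW replicate 1 and between -1.37 and 0.28 on the others. Among the 2013 identifiers changed at least 2-fold between conditions, 29 were very variable ones, 26 of them higher in SC.

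The identifiers fall into 10 series by their prefix, and the split of called identifiers into higher and lower differed from the rest in some of them. In the ENSORLT series, 138 of 607 tested identifiers rose and 53 fell, so that 72.3% of the called ones were higher in SC (Fisher's exact test against the other series, adjusted p = 1.04e-10, which treats identifiers as independent), and the series as a set was higher than the others (camera with a preset correlation of 0.01, adjusted p = 0.00543 over 10 series). That call was lost with an estimated correlation (adjusted p = 0.655). In the OLA series 141 rose and 259 fell of 1463 (camera adjusted p = 0.444), and in the olbr series 172 rose and 283 fell of 1421 (camera adjusted p = 0.444), so neither series as a set passed against the others. In fry, which asks whether a set moves one way on balance, 4 of the 10 series passed, with adjusted p of 0.0104 for ENSORLT, 0.0104 for olbr, 0.0107 for oleb and 0.0226 for olova, and OLA did not (0.0977). The split of the called identifiers by Fisher's exact test differed from the other series also for OLA (adjusted p = 5.48e-07), olbr (2.18e-05) and dola (0.0168). With the slide as a block, 88.9% of the called ENSORLT identifiers were higher in SC, and 50.9% of the OLA ones.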
